A study of Arabidopsis thaliana with 11 samples.

How the data were processed

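RNA was measured in 11-day-old seedlings of Arabidopsis thaliana, ecotype Columbia, grown under continuous light on medium with sucrose, per the labels' protocols, and sequenced from TruSeq libraries. The labels name 6 genotypes and 11 libraries, and each group was taken from the labels. The values used are RPKM, reads per kilobase of gene and per mega-read, as the authors deposited them in 1 table of 33602 genes with 1 column per genotype. The genome release was TAIR10, per the submitters' processing notes. The aligner, the counting tool, the handling of reads that map to several places and the way libraries of a genotype were combined are not given in the sources used here. Of the gene identifiers, 32835 matched the TAIR10.1 annotation used for symbols and coordinates. A single WT cell that held no number was treated as 0.

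The design fixed before the data were examined assumed 1 value per library and named limma tests, camera and fry tests of gene lists, a fit with the replicate number and fits that leave out a library. With 1 value per genotype none of these could be run, and every comparison is a description of these columns without a test or p-value. Values were compared on the log2(RPKM + 1) scale as deposited, a scale that understates the change of low genes. Genes of at least 1 RPKM in at least 2 of the 6 columns were compared, which left 19669, and a difference of at least 1 on the log2 scale was counted as 2-fold. The comparisons were each line against WT, MI12 against the mean of OE1 and OE2, OE3 against the same mean, and OE1 against OE2.

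Depth was recovered from the low values, which lie on steps worth 1 read divided by gene length. Between 73.5% (MI3) and 80.8% (OE1) of low values came out within 0.1 of a whole read, where 20% would by chance. A compared gene had a median of 1476 reads in WT and 764 in MI3. Intervals for ratios of single genes are 95% exact binomial intervals on the recovered reads. They cover counting error only, since reads without molecular identifiers are not independent molecules and the spread between plants is not in the table. In a simulation of the WT column with counting noise alone, over 19489 genes, 96.0% of 200 genes made 3-fold higher passed 2-fold, 0 of the unchanged genes did, and 0.0% of genes made 1.5-fold higher did.

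Gene lists were fixed before the data were examined, 29 in number, of which 28 had enough members in the table to be compared. The median of a list was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression, and a list among the lowest or highest 0.5% was said to stand apart. The rule for named genes, adapted to values without tests, took the 3 PTB genes, the 6 genes furthest above and the 6 furthest below with at least 5 RPKM in the higher column, the next 4 with a gene symbol on each side, and up to 3 members of each list past 2-fold, or up to 4 members of a list that stood apart. Comparisons without WT took 4 genes on each side. The rule as first written required an adjusted p-value and a minimum of 2 RPKM, which needed replicates.

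Near-identical values at copies of the 18S ribosomal RNA gene, 1391 RPKM at AT3G41768 and 1391 RPKM at AT2G01010 in WT, show that reads of such copies were not kept apart. Values of near-identical genes are therefore uncertain, among them PDF1.2, PDF1.2c and PDF1.3, bHLH38 and bHLH39, the Rubisco small subunit genes and the antenna genes. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes are uncertain too.

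Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter on low values, a filter of 5 RPKM in 2 columns, median-of-ratios scaling and quantile normalization. Alternatives chosen after seeing the data were the median of the other 4 lines as control, leaving out organelle and ribosomal RNA genes, and a minimum of 5 RPKM in the higher column. Overlaps between lines were set beside 100 simulations of unchanged lines. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.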

Results

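Gene expression was measured by RNA sequencing in 11-day-old seedlings of Arabidopsis thaliana, ecotype Columbia. The study asked how raised and lowered levels of the 3 polypyrimidine tract-binding protein homologues, PTB1, PTB2 and PTB3, affect the transcriptome, with splicing as its main readout. PTB proteins bind pyrimidine-rich stretches of RNA and regulate splicing. Splice variants were not analysed here, and all values below are totals per gene. The labels describe 6 genotypes and 11 libraries: wild type (WT), a line with an artificial miRNA against PTB1 and PTB2 (MI12), a line with an artificial miRNA against PTB3 (MI3), and lines overexpressing PTB1 (OE1), PTB2 (OE2) or PTB3 (OE3). MI3 has 1 library and each of the other 5 genotypes has 2. The table used here holds 1 RPKM value per gene and genotype, so there is no spread between replicates, no test and no p-value for any difference below. Each value is the authors' value for a genotype, and each fold change is a line minus WT on the log2(RPKM + 1) scale. From the steps between low values, the columns stood for about 93.1 M reads (mega-reads) in WT, 94.7 M in MI12, 46.4 M in MI3, 96.0 M in OE1, 79.5 M in OE2 and 89.6 M in OE3. The intervals given are 95% exact counting intervals, which cover counting error in those reads and no difference between plants.

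The first comparison checks the labels through the 3 targeted genes. PTB1 (AT3G01150, TAIR10.1 chromosome 3, 51496 to 54544) was at 9.46 RPKM in WT, 2.54 in MI12 and 603 in OE1. This put MI12 at 26.9% of WT, with a ratio of 0.269 and a counting interval of 0.240 to 0.300, and OE1 at 63.8 times WT, with an interval of 60.6 to 67.1. PTB2 (AT5G53180, chromosome 5, 21568131 to 21571904) was at 9.03 RPKM in WT, 4.01 in MI12, or 44.4% of WT, and 342.8 in OE2, or 38.0 times WT. PTB3 (AT1G43190, chromosome 1, 16275108 to 16278742) was at 19.5 RPKM in WT, 3.54 in MI3, or 18.15% of WT, and 65.4 in OE3, or 3.35 times WT. The targeted gene thus lay on the labelled side of WT in each of the 5 lines, on the log2 scale by -1.562 and -1.001 in MI12, -2.18 in MI3, 5.85 in OE1, 5.10 in OE2 and 1.69 in OE3. PTB1 and PTB2 were also each below WT where the other was overexpressed: PTB2 was at 5.74 RPKM in OE1, 63.6% of WT with a ratio interval of 0.593 to 0.682, and PTB1 at 6.49 RPKM in OE2, 68.7% of WT with an interval of 0.632 to 0.746. PTB3 stayed between 94.3% and 109.1% of WT in MI12, OE1 and OE2. These gene totals do not separate transgene from endogenous transcripts.

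**Figure D1:**
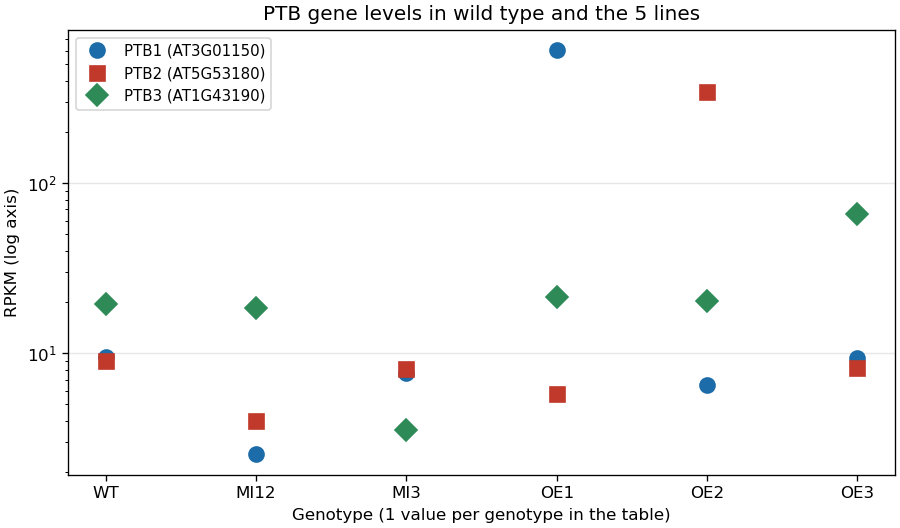
RPKM of PTB1, PTB2 and PTB3 on a log axis in the 6 genotypes, 1 value per genotype, without error bars because the table holds no replicates. PTB1 reaches 603 RPKM in OE1 and PTB2 342.8 RPKM in OE2, PTB3 reaches 65.4 RPKM in OE3, and the lowest value of each gene lies in the artificial miRNA line directed against it.

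Lowering PTB1 and PTB2 (MI12 against WT) left most genes near their WT level. Among 19669 genes compared, 46 were at least 2-fold higher and 53 at least 2-fold lower. The largest difference was at MIR319a (AT4G23713, chromosome 4, 12352956 to 12353131), a microRNA gene, with 0.121 RPKM in WT, about 2 reads, and 316 RPKM in MI12, a ratio of 2612 with a counting interval of 716.5 to 21390. The locus was also high in MI3, the other artificial miRNA line, at 261 RPKM, and at most 0.315 RPKM in the overexpressors. A response to lowered PTB1 and PTB2 is therefore not told apart here from an effect of the construct. Transcripts of the 12S seed storage proteins came next: CRU3 was at 1.03 RPKM in WT and 13.5 in MI12, and CRA1 at 2.79 and 23.8. Of the defensin genes, which are targets of jasmonate and ethylene signalling, PDF1.3 was at 29.2 RPKM in WT and 4.203 in MI12 and PDF1.2 at 57.1 and 22.5, while the jasmonate list that holds them had a median of 0.023, within the range of random lists, with 3 of 17 members at least 2-fold lower.

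A gene list was said to stand apart when its median lay among the lowest or the highest 0.5% of 10000 random lists of the same size, matched on mean expression. Heat shock genes had a median log2 fold change of -1.16, and 8 of 13 members were at least 2-fold lower. They included the small heat shock proteins HSP17.4 (6.54 RPKM in WT, 1.49 in MI12) and HSP17.6A (4.74 and 1.02). Flavonoid and anthocyanin genes had a median of -0.42, with chalcone synthase TT4 at 90.09 RPKM in WT and 40.4 in MI12, flavonol synthase FLS1 at 17.82 and 7.59, and chalcone isomerase TT5 at 13.2 and 6.23. Seed storage and embryo genes had a median of 1.79, with 2 of 4 compared members past 2-fold. Among genes of iron balance, whose median was 0.19, the iron store ferritin FER1 was lower (138 RPKM in WT, 51.4 in MI12) and the iron deficiency regulator bHLH38 higher (12.7 and 29.0). Photosynthetic antenna and Rubisco genes had a median of 0.32 without any member past 2-fold, and LHCB3 was at 949 RPKM in WT and 1579 in MI12, while the minor antenna gene LHCB4.3, outside that list, was at 19.8 and 4.27. Other named genes higher in MI12 were NAC044 (0.733 RPKM in WT, 5.80 in MI12), the tyrosine aminotransferase TAT3 (7.96 and 22.2), the cell wall protein AGP30 (4.01 and 11.4), MBP1 (1.95 and 5.90) and FAMT (2.099 and 5.85). ELIP1, an early light-induced protein, was lower (4.404 and 1.37). As measured facts beside these groups, chloroplast-encoded genes had a median of 0.49 in MI12, with 8 of 102 members at least 2-fold higher, and 18S ribosomal RNA (AT3G41768) was at 1391 RPKM in WT and 2325 in MI12, the highest of the 6 columns.

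In all, 12 of 28 lists lay outside the range of random lists in MI12, the PTB list itself among them, and the remaining ones were salicylic acid and pathogen defence (-0.17), touch, cold and rapid stress (-0.30), root tissue markers (0.17), root hair markers (0.25) and mitochondrially encoded genes (-0.19). The seed list rests on 4 genes of low abundance. Against the median of the other 4 lines in place of WT, the medians of the defence, touch and root hair lists had the opposite sign, the heat shock median was -0.38, and the flavonoid and phosphate medians were -0.78 and -0.64.

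MI3, the line with lowered PTB3 and only 1 library, had the largest differences from WT: 508 genes were at least 2-fold higher and 407 at least 2-fold lower. The share of higher genes among those was 55.5% as deposited, 48.5% after median-of-ratios scaling and 64.6% with the median of the other lines as control, so the larger side depends on the scaling. Genes of the phosphate starvation response led, with a median log2 fold change of 1.75 and 11 of 12 members at least 2-fold higher. The acid phosphatase PAP17 was at 24.1 RPKM in WT and 128 in MI3, the phosphate sensors SPX1 at 50.3 and 239 and SPX3 at 3.92 and 22.9, and the galactolipid synthase gene MGDC at 3.06 and 14.9. Outside that list, the ribonuclease RNS1 was at 3.17 RPKM in WT and 76.6 in MI3, the phosphatases PEPC1 at 13.2 and 98.6 and PS2 at 20.0 and 130, and the microRNA gene MIR399d, which targets a regulator of phosphate uptake, at 1.92 and 23.9. Root hair markers were higher as well, with a median of 1.25 and 6 of 8 members past 2-fold, among them the extensin-like LRX1 (10.4 RPKM in WT, 41.5 in MI3) and PRP3 (35.3 and 127).

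Several stress groups were also above WT in MI3. Abscisic acid and dehydration genes had a median of 0.77, with COR15A at 4.52 RPKM in WT and 49.0 in MI3, LTI78 at 17.0 and 71.1, KIN2 at 61.1 and 149, and the biosynthetic gene NCED3 at 1.55 and 5.52. Late anthocyanin genes were higher, with LDOX at 1.76 and 9.77 RPKM, DFR at 2.02 and 9.19 and the glutathione transferase GSTF12 at 1.39 and 7.26, and the flavonoid list had a median of 0.40. Glucosinolate genes had a median of 0.59 with none of 14 members past 2-fold, and BCAT4 was at 46.0 RPKM in WT and 83.7 in MI3. Senescence genes had a median of 0.49, with the transcription factor NAP at 9.32 and 36.8 RPKM. Beta-amylase BAM5 (4.49 and 70.5), RTFL12 (3.64 and 29.8) and PYD4 (2.73 and 22.9) were further named genes with higher values. PIL2, a phytochrome-interacting factor, was at 5.38 RPKM in WT and 11.8 in MI3.

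Below WT in MI3 were heat shock genes (median -0.97, 6 of 13 at least 2-fold lower), iron genes (median -0.62) and defence genes (median -0.46). The iron deficiency regulators BHLH100 (8.88 RPKM in WT, 0.767 in MI3) and bHLH38 (12.7 and 1.78) and the iron transporter IRT1 (7.92 and 1.46) were low. The defence gene BGL2, a glucanase, was at 53.6 and 9.77 RPKM and WRKY18 at 49.2 and 11.99. The defensins PDF1.3 (29.2 and 2.23) and PDF1.2 (57.1 and 7.62) belong to a jasmonate list whose median of 0.17 lay within the range of random lists. Single genes far below WT were the copper protein BCB (153 and 9.09), PHI-1 (84.3 and 4.94), the calmodulin-like TCH3 (402 and 51.5), the cell wall enzyme TCH4 (342 and 57.7), DIN10 (653 and 82.6), the abscisic acid receptor PYL5 (70.2 and 8.99) and the expansin-like EXLA1 (126 and 17.1). The touch, cold and rapid stress list, which holds TCH3 and TCH4, had a median of 0.068, within the range of random lists. Of its 11 compared members, 2 were at least 2-fold lower and 2 at least 2-fold higher. The Rubisco small subunit genes RBCS3B (2867 and 1063), RBCS1B (1006 and 390) and RBCS2B (1538 and 690) were lower, whereas the antenna and Rubisco list as a whole had a median of -0.34 and lay within the range of random lists. MIR319a was at 261 RPKM in MI3, a ratio to WT of 2158 with a counting interval of 591 to 17670. As measured facts, root tissue markers had a median of 0.17, seed storage genes -0.61, chloroplast-encoded genes 0.20 and mitochondrially encoded genes 0.38, and 18S ribosomal RNA was at 1197 RPKM. MI3 stands for 1 library of 46.4 M reads, so a difference of that library from the rest cannot be told from a difference of the genotype. With the median of the other lines as control, the heat shock median was 0.09 in place of -0.97, the chloroplast median -0.17 and the defence median -0.093, the heat shock and defence values within the range of random lists, while the phosphate median was 1.48.

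Overexpression of PTB1 (OE1 against WT) put 61 genes at least 2-fold higher and 118 at least 2-fold lower. Iron deficiency regulators were above WT: BHLH100 was at 8.88 RPKM in WT and 38.7 in OE1, bHLH39 at 10.6 and 35.5, bHLH38 at 12.7 and 36.2 and BHLH101 at 5.06 and 12.2. The list of iron balance genes that holds them had a median of 0.53 with 4 of 13 members past 2-fold. The receptor-like kinase CRK28 was at 6.71 RPKM in WT and 31.2 in OE1, and the seed storage genes CRA1 and CRU3 at 12.7 and 6.18 RPKM in OE1, in a seed storage list with a median of 1.32 and 2 of 4 members past 2-fold. Genes far below WT were alcohol dehydrogenase ADH1 (45.1 and 10.7), sucrose synthase SUS4 (15.0 and 2.73), AT4G33070 (24.1 and 4.02) and FTM1 (20.4 and 2.21). The metallothionein MT1B was at 203 RPKM in WT and 37.8 in OE1, and the chitinase HCHIB at 21.1 and 4.79.

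Root genes were below WT in OE1. Root tissue markers had a median of -0.59, with BGLU22 at 23.8 RPKM in WT and 10.4 in OE1 and the Casparian strip gene CASP1 at 9.99 and 4.69. Root hair markers had a median of -0.41 and phosphate starvation genes a median of -0.39, with the non-coding RNA gene IPS1 at 19.1 and 8.31 RPKM and the transporter PHT1;1 at 21.7 and 11.5. The glucosinolate list had a median of -0.30, with 2 of 14 members at least 2-fold lower, CYP79F1 at 26.1 and 10.5 and CYP83A1 at 63.9 and 31.3. Outside the range of random lists lay also circadian clock genes (median 0.27, LHY at 24.6 and 39.1 RPKM), light signalling (0.21), senescence (0.22), cell division (-0.26), defence (-0.27), abscisic acid (-0.21), touch and cold (-0.41), mitochondrially encoded (-0.24) and chloroplast-encoded genes (0.33), to make 15 lists. No member of the clock, light signalling, senescence or cell division lists was 2-fold apart. CYP71A13, a phytoalexin gene of the defence list, was on the other side of WT, with 5.34 RPKM in WT and 14.6 in OE1. FLC, a repressor of flowering, was at 0.249 RPKM in WT and 1.74 in OE1, both low values, and ORS1 at 3.20 and 11.2. AT4G12160 was at 14.6 RPKM in WT and 0.07 in OE1, and between 10.4 and 18.5 in the other 4 lines. The heat shock list had a median of -0.17 and lay within the range of random lists, but was at 0.93 and outside it against the median of the other lines. When the median of the other lines replaced WT, 246 genes were lower, and the defence (0.019), touch and cold (-0.024), senescence (0.056) and chloroplast (0.0089) medians lay within the range of random lists.

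Overexpression of PTB2 (OE2 against WT) put 51 genes at least 2-fold higher and 36 at least 2-fold lower. After PTB2, the lipid transfer protein gene LTP4 (1.47 RPKM in WT, 11.5 in OE2), BAM5 (4.49 and 25.6), MLO7 (0.963 and 6.12), CRK28 (6.71 and 21.8), ELI3-2 (2.94 and 10.6), PMEI2 (1.23 and 5.46) and PYD4 (2.73 and 9.33) were highest among genes with a symbol. Ferritin FER1 was at 138 RPKM in WT and 40.5 in OE2, and with IRT1 (7.92 and 3.35), FRO2 (2.70 and 1.11) and FER3 (38.4 and 21.2) it belonged to an iron list with a median of -0.69. The organ size genes ARGOS (23.4 and 7.96) and ARL (50.6 and 18.0) were both low, as were the jasmonate-degrading CYP94C1 (8.43 and 3.22) and AIR1 (10.8 and 4.44). Heat shock genes had a median of -0.79, with the chaperone HSP90.1 at 34.4 and 16.1 RPKM and ROF2 at 13.0 and 5.17.

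Phosphate starvation genes had a median of 0.37 in OE2, none past 2-fold, with MGDC at 3.06 and 6.83 RPKM. The salicylic acid marker PR1 was at 30.0 RPKM in WT and 60.6 in OE2 and WRKY33 at 20.5 and 39.4, within a defence list whose median was 0.17. Abscisic acid genes had a median of 0.16, touch and cold genes -0.22, clock genes -0.17, seed storage genes 0.37 and chloroplast-encoded genes 0.34, which completed the 9 lists outside the range of random lists. The senescence marker SAG13 was at 9.09 and 22.7 RPKM. All genes together had a median of -0.05 in OE2, and the share of higher genes among those past 2-fold was 58.6% as deposited, 71.8% after median-of-ratios scaling and 72.9% after quantile normalization. Against the median of the other lines, the heat shock and touch medians of OE2 were 0.08 and 0.10, the seed median -0.38 and the phosphate median 0.0082, and the last 3 lay within the range of random lists. The defence median was 0.62 and the chloroplast median 0.0011 with that control.

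Overexpression of PTB3 (OE3 against WT) put 99 genes at least 2-fold higher and 104 at least 2-fold lower. Heat shock genes were lower in OE3 than in the other 4 lines, with a list median of -1.68 and 9 of 13 members at least 2-fold below WT. HSP17.4 was at 6.54 RPKM in WT and 0.739 in OE3, HSP17.8 at 6.64 and 0.998, HSP90.1 at 34.4 and 8.53 and HSP70 at 56.4 and 14.5. Phosphate starvation genes were above WT, with a median of 0.95 and 5 of 12 members past 2-fold, including SPX1 (50.3 and 109), PAP17 (24.1 and 52.9), IPS1 (19.1 and 45.0) and MGDC (3.06 and 9.60). RNS1 (3.17 and 19.1), MIR399d (1.92 and 13.9), PEPC1 (13.2 and 40.7) and PS2 (20.0 and 58.9), high in MI3, were high in OE3 as well.

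Root hair markers had a median of 0.81 in OE3, with PRP1 at 7.98 and 22.5 RPKM, and root tissue markers a median of 0.34, with BGLU21 at 28.0 and 59.1. BAM5 (4.49 and 35.8), ST4B (5.06 and 21.6), CEP2 (10.7 and 37.2) and the sulfur deficiency gene ATSDI1 (3.48 and 12.2) were further genes above WT. Defence genes had a median of -0.54, with BGL2 at 53.6 and 20.1 RPKM, PR1 at 30.0 and 15.3 and WRKY70 at 24.6 and 12.1. The defensins PDF1.3 (29.2 and 3.32) and PDF1.2 (57.1 and 18.4), the anion channel gene SLAH3 (56.1 and 13.5), PHI-1 (84.3 and 19.2) and the iron-sulfur protein gene NEET (49.9 and 13.7) were below WT. Touch and cold genes had a median of -0.60, abscisic acid genes -0.26, iron genes -0.38, jasmonate genes -0.17, splicing factors of the SR family -0.14, seed storage genes 0.58 and chloroplast-encoded genes 0.31, to make 12 lists. No SR member was 2-fold apart, and RSZ22 was at 23.608 and 19.0 RPKM. With the median of the other lines as control, 41 genes were higher and 30 lower, and the heat shock median was -0.71, the seed median -0.18 and the chloroplast median -0.028. With a filter of 5 RPKM in 2 columns the jasmonate median was 0.049.

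**Figure D2:**
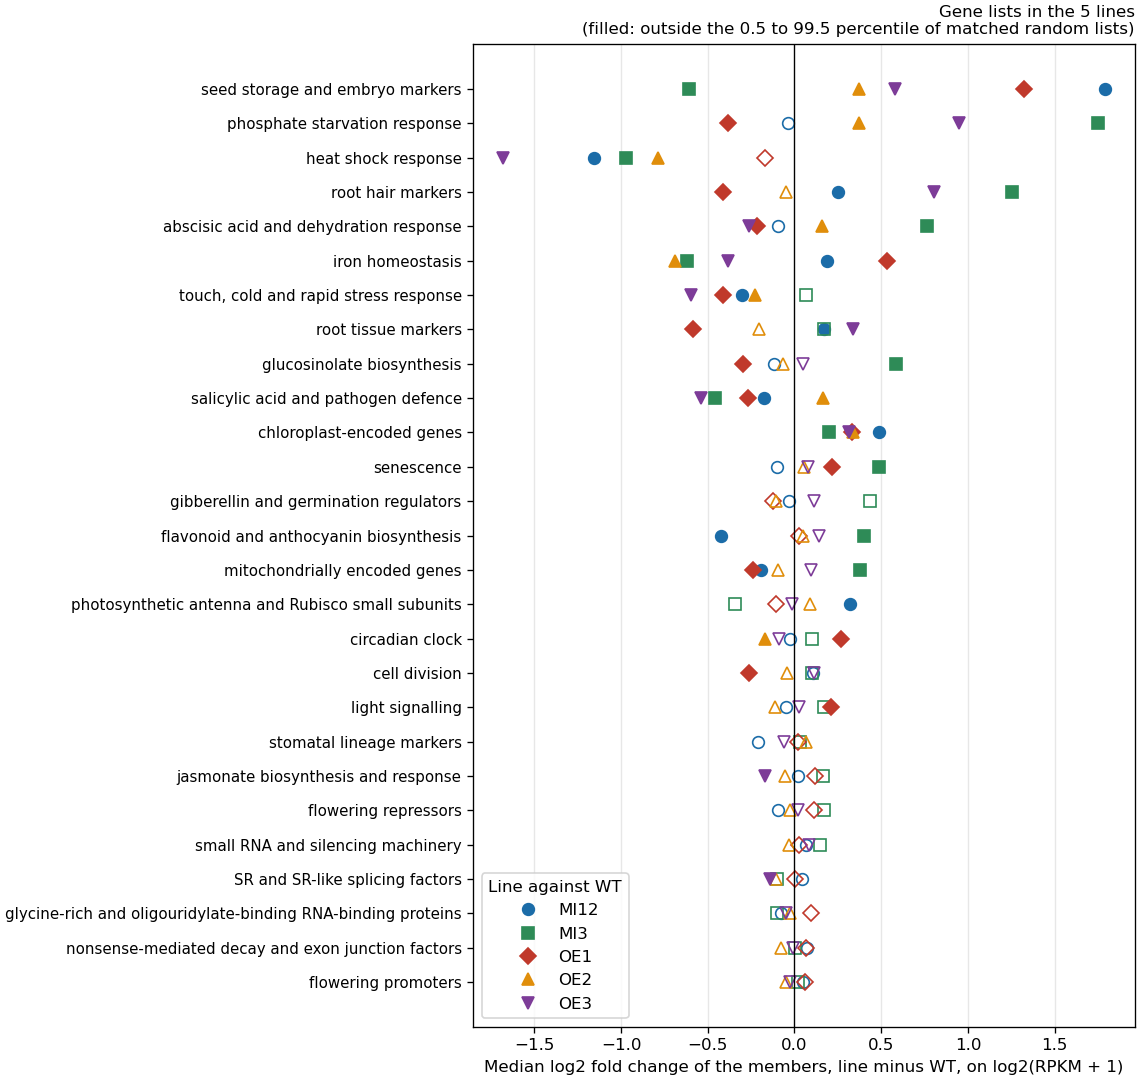
Median log2 fold change on the log2(RPKM + 1) scale of 27 gene lists in each of the 5 lines against WT. Filled symbols lie among the lowest or highest 0.5% of matched random lists. Phosphate starvation genes lie at 1.75 in MI3 and 0.95 in OE3, and heat shock genes at or below -0.79 in MI12, MI3, OE2 and OE3 and at -0.17 in OE1, whereas flowering, decay and silencing lists lie near 0.

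With WT as control, lists within the range of random lists in each of the 5 lines were flowering promoters, flowering repressors, nonsense-mediated decay and exon junction factors, glycine-rich and oligouridylate-binding RNA-binding proteins, and the small RNA and silencing machinery. Their medians lay between -0.10 and 0.17. The same held for gibberellin and germination regulators, with medians from -0.12 to 0.43, and for stomatal lineage markers, with medians from -0.21 to 0.07. Against the median of the other lines, flowering promoters (-0.090) and repressors (-0.13) in OE3, gibberellin regulators in MI3 (0.55) and stomatal markers in MI12 (-0.22) and OE2 (0.29) lay outside that range. In all, 60 of 140 list values lay outside the range, where 1.4 are due if lists were random draws. Members of a list are regulated together, which random lists are not, so this excess is no measure of significance.

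Lowered against raised PTB1 and PTB2 was compared without WT, as MI12 against the mean of OE1 and OE2. MI12 had 64 genes at least 2-fold higher and 88 at least 2-fold lower, or 42.1% higher, and 54.1% with a pseudocount of 0.1. Apart from the PTB genes and MIR319a, CRK28 was the gene furthest below, with 2.53 RPKM in MI12, 31.2 in OE1 and 21.8 in OE2, and AT4G25707 followed with 2.04, 10.2 and 16.1. The flowering repressor list lay within the range of random lists, with a median of 0.07 and 1 of 8 members higher and 1 lower. FLC was at 0.033 RPKM in MI12, 1.74 in OE1 and 1.02 in OE2, and its relative MAF1 at 8.72, 3.98 and 3.65. The light stress genes ELIP2 (0.839 in MI12, 4.48 in OE1, 3.91 in OE2) and ELIP1 (1.37, 5.24 and 3.76) were lower in MI12, and the antenna gene LHCB2.2 higher (685, 320 and 290). After MIR319a, AT4G12160, AT5G10040 and AT4G03926 were furthest above, and each was low in OE1, at 0.07, 0.192 and 0.657 RPKM. Lists with positive medians were seed storage (0.69), root tissue (0.59), root hair (0.52), antenna and Rubisco (0.48), cell division (0.25) and chloroplast-encoded genes (0.16). Those with negative medians were heat shock (-0.61), flavonoid (-0.52), senescence (-0.35) and stomatal lineage (-0.28), beside the PTB list.

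A reciprocal response was sought among genes that differed from WT by at least 0.5 on the log2 scale in MI12, OE1 and OE2 alike. Of 109 such genes, 11 lay on one side of WT in MI12 and on the other in both overexpressors, where random signs would give 27.25. All 11 were below WT in MI12 and above it in OE1 and OE2. The set was defined after the values were seen. Another 79 genes lay on the same side of WT in all 3 lines. The shared WT column favours the same side, so fewer opposite genes than with random signs are due without any response. That lower count was not computed, so whether 11 is an excess cannot be told. CRK28 was one of the 11. The others included the histone deacetylase HDA14 (8.45 RPKM in WT, 4.87 in MI12, 15.3 in OE1, 13.1 in OE2), the non-coding RNA gene GUT15 (69.7, 43.1, 104 and 107), ESM1 (106, 58.7, 152 and 153), MLO7 (0.963, 0.258, 3.07 and 6.12), ELIP2, and RBCS1B (1006, 704, 1531 and 1442).

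Raised PTB3 was set against raised PTB1 and PTB2 as OE3 against the mean of OE1 and OE2. OE3 had 227 genes at least 2-fold higher and 88 at least 2-fold lower, or 72.1% higher as deposited and 60.5% after median-of-ratios scaling and 60.3% after quantile normalization. The phosphate list had a median of 0.86, with IPS1 at 45.0 RPKM in OE3, 8.31 in OE1 and 18.8 in OE2, and MIR399d, outside that list, was at 13.9, 1.14 and 4.36. Root hair markers had a median of 1.04 and root tissue markers 0.73, with BGLU21 at 59.1 RPKM in OE3, 18.0 in OE1 and 22.4 in OE2. Heat shock genes had a median of -1.20, defence genes -0.48 and iron genes -0.44, with PDF1.3 (3.32, 38.8 and 12.2) and PDF1.2c (9.85, 69.8 and 25.9) furthest below and PR1 at 15.3, 34.1 and 60.6. The dehydrin RAB18 was at 3.84 RPKM in OE3, 9.76 in OE1 and 10.9 in OE2. Glucosinolate (0.24), cell division (0.26), mitochondrially encoded (0.24), abscisic acid (-0.20), touch and cold (-0.34), senescence (-0.37) and chloroplast-encoded genes (-0.04) completed the 14 lists with the PTB list.

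The 2 close homologues were compared directly as OE1 against OE2, where 74 genes were at least 2-fold higher in OE1 and 114 higher in OE2. Genes of iron balance were higher in OE1, with a list median of 0.93 and 6 of 13 members past 2-fold. All 13 members were higher in OE1 than in OE2, the ferritins among them, so the median is no measure of iron deficiency alone. Of the iron deficiency genes, BHLH100 was at 38.7 RPKM in OE1 and 5.14 in OE2, bHLH39 at 35.5 and 5.82, and IRT1 at 12.03 and 3.35. Heat shock genes (median 0.57), light signalling (0.37) and clock genes (0.27) were also higher in OE1, with CCA1 at 32.4 and 17.1 RPKM. Phosphate genes were lower in OE1 (median -0.81, SPX3 at 2.06 and 7.34), as were defence genes (-0.51, WRKY33 at 18.4 and 39.4), abscisic acid genes (-0.27, RD22 at 27.4 and 73.3) and TCH4 (170 and 440). MT1B was at 37.8 RPKM in OE1 and 211 in OE2. AT2G01021, a locus beside the ribosomal RNA genes of chromosome 2, was at 25.4 and 326 RPKM, and in the other columns between 19.7 in MI3 and 304 in MI12. The ribosomal RNA gene AT2G01020 was likewise at 147 RPKM in OE1 and 497 in OE2, with 146 in MI3 and 570 in MI12. The difference at AT2G01021 was not told apart from one in ribosomal RNA content. The remaining lists outside the range were seed storage (0.48), root tissue (-0.29), root hair (-0.39), glucosinolate (-0.21), flavonoid (-0.25), cell division (-0.21) and mitochondrially encoded genes (-0.11), which made 14.

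**Figure D3:**
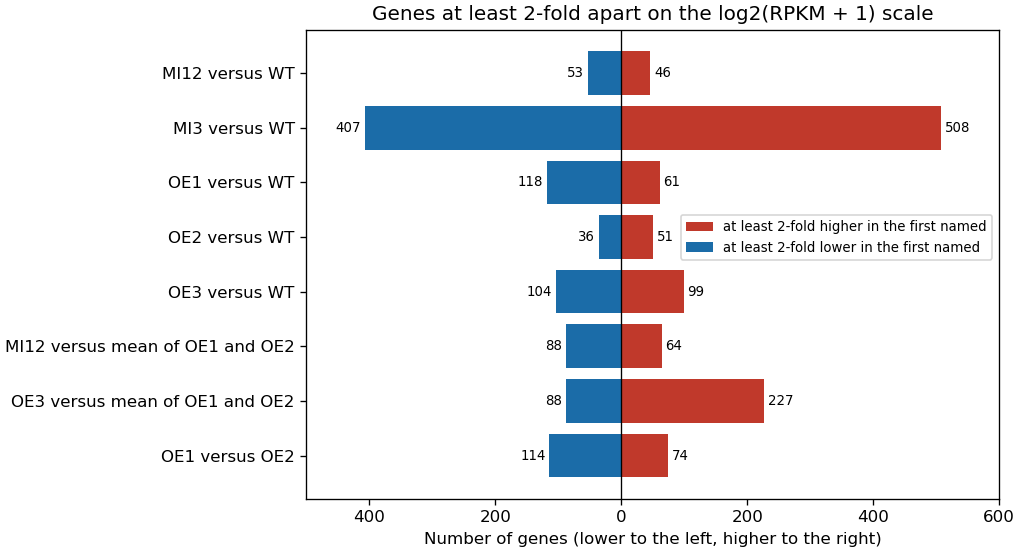
Number of genes at least 2-fold higher (right) or lower (left) in the first named side of each comparison, on the log2(RPKM + 1) scale, among 19669 genes. MI3 against WT has 508 higher and 407 lower genes, and OE2 against WT 51 and 36.

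MI3 and OE3, which carry lowered and raised PTB3, shared more genes than any other pair with WT as control. In both lines 69 genes were at least 2-fold higher, where independent lists would share 2.56, and 76 at least 2-fold lower, where independent lists would share 2.15. Independent lists leave out the shared WT column, and simulated lines with no change that share the WT reads had 0.04 and 0.02 such genes. With a different column as control for each line, over 12 choices made after seeing the data, 40 to 254 genes were higher in both and 30 to 65 lower in both. No gene was higher in MI3 and lower in OE3, and 2 were lower in MI3 and higher in OE3. PTB3, the gene targeted in both lines, was 1 of these 2. The correlation of their fold changes across genes was 0.69, which treats genes as if they were independent, and the covariance was 0.0891, beside 0.00193 in 100 simulations of unchanged lines that share the WT reads. Those simulations hold counting error alone and understate what a shared WT adds. With those separate controls the correlation was 0.38 to 0.64. The upper ends, 254 genes and 0.64, have OE1 and OE2 as the controls. With its sign turned, the same contrast gives the upper end of 0.64 for OE1 with OE2. It therefore cannot tell a likeness of MI3 and OE3 from a likeness of OE1 and OE2. MI3 and OE1 ran against each other, with a correlation of -0.14 and 37 genes higher in MI3 and lower in OE1, where independent lists would share 3.05. ADH1, SUS4, HCHIB, MT1B, LTI78, BGLU22 and IPS1 were among those 37. The correlation was 0.42 for OE1 with OE2, with 0.061 to 0.64 under separate controls, and 0.46 for MI12 with OE3, with -0.51 to 0.36. It was 0.28 for MI12 with MI3, 0.15 with OE1 and 0.24 with OE2, 0.18 for MI3 with OE2, 0.09 for OE1 with OE3 and 0.29 for OE2 with OE3. Each of these 8 lay below the simulated correlation of its pair for unchanged lines that share the WT reads, which was 0.39 to 0.50 over the 10 pairs. The covariances of the same 8 pairs lay above the simulated 0.0019, from 0.0070 for OE1 with OE3 to 0.0322 for MI12 with MI3. As the simulations hold counting error alone, these measures leave open whether those pairs share more than unchanged lines would.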

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

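The tests of a shared WT column and of a larger share of roots were planned before their results were seen, and the tests of the PTB3 level and of roots in OE3 were chosen afterwards. The differences below are between lines, each line against the same WT column. Because both lines' lists stood apart from random lists with opposite signs, they were singled out, and the differences themselves were not tested, as there are no replicates.

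Phosphate starvation genes differed in direction between overexpressors: the list median of OE1 minus that of OE2 was -0.75, and of OE1 minus OE3 -1.33. The same genes stood above WT in both MI3 and OE3. A WT column that stood low is argued against as the cause, since against the median of MI12, OE1 and OE2 the list stayed at 0.91 in OE3 (95% bootstrap interval over members 0.56 to 1.28) and 1.71 in MI3 (1.52 to 2.19). A larger share of root tissue is argued against as the whole cause, since the phosphate median exceeded the root tissue median by 1.58 in MI3 (0.37 to 1.96) and by 0.61 in OE3 (0.097 to 0.90). In MI3, however, 3 of 10 root tissue members were at least 2-fold higher and 7 lay above WT. In OE3 all 10 lay above WT, 1 of them past 2-fold. A larger share of root tissue as part of the cause stays open. Root hair markers were also higher, at 1.25 and 0.81. The phosphate list was not set against the root hair list, so a larger share of root hairs stays open. Whether the PTB3 level is the cause stays open. OE3 at 0.95 lay on the same side as MI3 at 1.75, although PTB3 was raised in OE3 and lowered in MI3. The table holds no spread between replicates, and MI3 has only 1 library. Shifts to the same side in both lines would not by themselves decide the cause. Phosphate supply, growth and handling of the plants were not tested.

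Iron genes had a median difference of 1.22 for OE1 minus OE2, 0.92 for OE1 minus OE3 and 0.81 for MI12 minus MI3. Root tissue markers differed by -0.92 and root hair markers by -1.22 for OE1 minus OE3. Defence genes of the salicylic acid list differed by -0.44 for OE1 minus OE2 and by 0.71 for OE2 minus OE3. Abscisic acid genes differed by -0.37 for OE1 minus OE2 and by 0.42 for OE2 minus OE3, and clock genes by 0.44 for OE1 minus OE2. Between the artificial miRNA lines, MI12 minus MI3 was -0.82 for flavonoid genes, 2.40 for seed storage genes and -0.57 for mitochondrially encoded genes.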

How the results depend on the processing

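The median of the other lines as control, the removal of organelle and ribosomal RNA genes and the 5 RPKM minimum in the higher column were chosen after seeing the data, as were quantile normalization and the 5 RPKM filter for gene lists. No paired analysis was possible because the table holds 1 column per genotype and carries no replicate number. For the same reason the limma, camera and fry fits, their spread settings, fits that leave out a library and the split of the WT libraries were not run. Of 270 named results past 2-fold, 258 stayed past it with the same sign under median-of-ratios scaling, and 256 under quantile normalization. With the other lines as control 120 of 186 did, and 6 changed sign. The 1 library of MI3 at 46.4 M reads limits what can be said of low genes there. The cause of the differences below was not tested, except that a smaller pseudocount enlarges the folds of low genes by its construction.

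With a pseudocount of 0.1, the genes at least 2-fold higher and lower numbered 104 and 119 in MI12, 118 and 302 in OE1, 131 and 96 in OE2 and 225 and 178 in OE3, and 834 were higher in MI3. MI12 against the mean of OE1 and OE2 gave 211 and 179, OE3 against that mean 599 and 167, and OE1 against OE2 127 and 234. PTB1 was then at -1.85 in MI12 and 5.98 in OE1, PTB2 at -1.15 in MI12 and 5.23 in OE2, and PTB3 at -2.43 in MI3. With a pseudocount of 0.5, higher genes numbered 72 in MI12, 85 in OE2, 114 in MI12 against the mean of OE1 and OE2 and 350 in OE3 against that mean, and PTB2 was at 5.17 in OE2. At 5 RPKM in at least 2 columns, where fewer genes are compared, higher genes numbered 29 in MI12, 33 in OE1 and 31 in OE2, and the jasmonate median of OE3 was 0.049. At 5 RPKM in the higher column, 37 were higher in OE1. After quantile normalization, 23 genes were lower in OE2, PTB1 was at 5.93 in OE1 and PTB2 at 4.998 in OE2. The larger side of the counts changed for MI3 after median-of-ratios scaling (48.5% higher), for MI12 without a filter (50.47%) and after quantile normalization (50.52%), for OE3 with pseudocounts of 0.1 (55.8%) and 0.5 (51.4%) and the other lines as control (57.7%), and for MI12 against the mean of OE1 and OE2 with a pseudocount of 0.1 (54.1%).

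With the median of the other lines as control, 246 genes were lower in OE1, and 41 were higher and 30 lower in OE3. PTB1 was at 6.22 in OE1, and PTB2 at -0.87 in MI12 and 5.46 in OE2. Of 60 list medians outside the range of random lists against WT, 48 lay outside it with this control too and 11 changed sign: defence in MI12 (0.19) and OE1 (0.019), heat shock in MI3 (0.09) and OE2 (0.085), touch and cold in MI12 (0.12) and OE2 (0.10), root hair in MI12 (-0.11), seed storage in OE2 (-0.38) and OE3 (-0.18), and chloroplast-encoded genes in MI3 (-0.17) and OE3 (-0.028). Of the 48, 4 lay outside the range with the opposite sign: defence in MI12, heat shock in OE2 and chloroplast-encoded genes in MI3 and OE3. Of 80 within the range against WT, 15 lay outside it and 14 changed sign. Both held for heat shock in OE1 (0.93) and senescence (-0.22) and flowering repressors (-0.13) in OE3. Single genes that changed sign were HSP17.6II in MI3 (0.09) and OE2 (0.29), PDF1.3 (1.47), HSP90.1 (0.085) and CRA1 (-0.40) in OE2, and ATCG00390 in OE3 (-0.29).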

Other observations

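All tests in this part, and the hypoxia list and the miR319 target list, were chosen after the values had been seen. A list of 15 genes induced by low oxygen, drawn up after ADH1 and SUS4 had been seen far below WT in OE1, had a median log2 difference from WT of 1.16 in MI3, with 11 members at least 2-fold higher, and of -0.75 in OE1, with 6 at least 2-fold lower. Among those 6 were ADH1, SUS4, AT4G33070 and FTM1, already seen low, and these 4 and ERF71 had been seen among the genes higher in MI3 and lower in OE1, so neither the OE1 nor the MI3 value is an independent observation. It was -0.56 in OE2, -0.20 in MI12 and -0.02 in OE3. AT4G12160 was at 0.07 RPKM in OE1 against 14.6 in WT. AT2G01021, beside the ribosomal RNA genes, was at 121 RPKM in WT, 304 in MI12, 19.7 in MI3, 25.4 in OE1, 326 in OE2 and 38.9 in OE3. The ribosomal RNA gene AT2G01020 was at 328, 570, 146, 147, 497 and 188 RPKM in the same order.

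Heat shock genes lay below WT in MI12, MI3, OE2 and OE3, and near it in OE1. Scaling of the columns is argued against, since after median-of-ratios scaling the list median was still -1.16 in MI12 (95% bootstrap interval over members -1.51 to -0.69) and -1.70 in OE3. A WT column that alone stood high is argued against as the whole cause in OE3, since OE3 stood at -0.71 against the median of the other 4 lines (-0.81 to -0.49), where random lists ranged from -0.08 to 0.21. In MI12, MI3 and OE2 that median was -0.38, 0.09 and 0.08, not low enough for the bound in all 3, so a high WT value stays open there. The spread between plants is not in the table. The PTB1 and PTB2 level stays open too: OE2 at -0.79 lay on the same side as MI12 at -1.16, and the table holds no replicate spread to set beside these values.

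MIR319a was high in both artificial miRNA lines, with about 5267 reads in MI12 and 2131 in MI3 beside 2 in WT and at most 5 in the overexpressors. Raised activity of mature miR319 in MI12 is argued against, since the median of its 5 TCP targets was -0.057 (-0.18 to 0.04), whereas in MI3, at -0.66 (-1.04 to -0.12), it stays open. In OE3, where MIR319a was at 0.315 RPKM, TCP10 and TCP4 were also below WT, at -0.60 and -0.35. The median of the 5 targets in OE3 was -0.046, with 2 of them above WT. A candidate explanation is that the artificial miRNAs were built in a MIR319a precursor, whose transcript would be read at this locus. It stays open. MIR319a was at 2612 times WT in MI12 (counting interval 716.5 to 21390) and 2158 times in MI3 (591 to 17670), ratios that rest on 2 reads in WT and that prompted the explanation. MIR319b and MIR319c were at most 1.39 times WT in both lines, with intervals that reach 4.887, and MIR319a at most 2.60 times WT in the overexpressors, with an interval that reaches 27.3. Raised transcription of MIR319a itself would give the same values at these loci. In MI12 the TCP median of -0.057 argues against such a rise with active mature miR319. The construct's sequence was not used here.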
